A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

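Ribosome profiling, which sequences the RNA fragments covered by ribosomes, was carried out on Escherichia coli K-12 MG1655. Per the labels' protocols, cells grew with air at 37 °C in MOPS rich medium with 0.2% glucose and received chloramphenicol 2 min before harvest. Monosomes were collected on spin columns, ribosomal RNA was depleted with a kit, and transfer RNA was removed during library construction. The samples form 1 group of 2 biological replicates, and no untreated or otherwise grown sample was analysed here.

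The deposited values are signal per nucleotide and strand over 4639675 positions of the chromosome, with 1 file per replicate. cutadapt 1.3 and Bowtie 1.0.0 are named in the submitters' processing notes, without settings. The genome build, the limits on read length and the treatment of reads that match several places are not given in the sources used here. Runs of signal summed to whole numbers, with deviations of at most 3.75e-07 in replicate 1 and 1.30e-06 in replicate 2, so the values were not scaled to library size and sums of signal were taken as reads. All runs with a sum of 1 (within 1e-06), 19531 and 27953 in the replicates, consisted of N values equal to 1/N within a relative tolerance of 1e-05, so these lone reads were spread evenly over consecutive positions. How reads in other runs were spread was not tested. Replicate 1 held 6418583 reads and replicate 2 held 8615848 reads. At these depths, a count of 0 (a limit of 3 counts) allows a share of up to 4.67e-05% of the reads in replicate 1 and 3.48e-05% in replicate 2. Reads amplified by PCR without molecular identifiers are not independent molecules, so all intervals and limits cover counting error only. P-values measure only the spread between these 2 samples, pooled in part over all regions tested together.

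No genome sequence or annotation of the files' build was used. A table of gene names belonged to the assembly ASM584v2, whose coordinates run past the last position of the files, so no gene name was assigned to any region and none of its coordinates was used. The comparisons had been laid out per gene before the data were examined. They were carried out on features taken from the signal instead: windows of 300 nt on each strand, and clusters, which are runs of signal in either replicate joined over gaps of at most 50 nt. A cluster was kept with at least 100 reads in each replicate. Density is given as reads per kb per 1000000 reads of the library, since the total over coding sequences, the planned scale, could not be formed. The window length, the gap and the read minimum were chosen after other values had been looked at.

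Windows were measured where the density was at least 5 in each replicate. Their log2(density + 1) values, less the median of each replicate, were tested with an intercept-only model in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment. limma moderates the variance of each region with that of all regions in the test, so its SEs and p-values are not the spread of a named region alone. A window was called with an adjusted p under 0.05 and a density at least 4 times above or below the median in both replicates. Differences are on the log2(density + 1) scale, which understates the range of low windows. Because a window is set against the median of all windows in the same library, this test describes levels within the samples and compares no conditions. The interval of the replicate correlation came from 200 resamplings of 100-kb blocks.

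For the distribution along clusters, the mean signal from nt 16 to 150 was divided by that of the rest up to 15 nt from the other end, after adding 0.1 times the cluster's mean to both, in clusters of at least 450 nt with density at least 20 in each replicate. These limits are those laid out beforehand for codons 6 to 50 of a gene. The ratio had first been computed without leaving out the ends and with at least 500 reads per cluster, which gave a lower median, and the limits laid out beforehand were then restored. The log2 ratios were tested with limma as above. The same ratio at the 3′ end was added after the data were examined. Peaks were positions with at least 10 times the cluster's mean signal, at least 30 nt from both ends, in clusters with density at least 50. Peaks within 30 nt were merged, shared peaks were ranked by the lower of their values in the 2 replicates, and the overlap by chance came from 100 random shifts of the positions within their clusters.

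The share of signal per reading frame, which needs annotated genes, was replaced by a Fourier measure chosen after the data were examined. Each cluster was divided into pieces of 300 nt, pieces with at least 50 reads in each replicate were kept, and the phase of log2(signal + 0.5) at a period of 3 nt was compared between adjoining pieces. Phases within 60° counted as the same, which chance gives in 33.3% of pairs. The same was done at 8 control periods from 2.86 to 3.16 nt.

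The procedures were tested on simulated data. Of 100 windows set to 8 times the median among 8226 windows, 96.0% were called over it, and of 100 set to an eighth, 83.0% were called under it. In these data the median density was 44.7 in replicate 1 and 43.2 in replicate 2. The windows set low thus lie close to the density limit of 5. How many such windows would pass that limit was not tested, so 83.0% may overstate their recovery. None of 200 windows set to the median was called. A call needs a density 4 times above or below the median in both replicates, which made this result likely by design. A 4-fold excess in the first 150 nt of 60 simulated clusters gave a median log2 ratio of 1.85, and 100% of 60 simulated peaks were found at the exact position with 0 false peaks. In the peak simulation each read lay at a single position over an even background, so this recovery was near certain by design. Reads here were often spread over several positions, so the accuracy of positions and the rate of false peaks in these data were not tested. Simulated clusters with a reading frame kept the phase in 95.8% of 240 adjoining pairs, and those without one in 33.8%.

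The regions named follow the rule fixed for genes before the data were examined, applied to clusters: the 20 densest and 5 least dense, the 10 highest and 5 lowest called ratios for the first 150 nt, and the 10 highest shared peaks. Of these, those that matter are given in full. Clusters that differed most between replicates, windows with the highest signal, and clusters with much signal on the opposite strand were named after their values were seen. The same holds for clusters named with their 3-nt phase. Shares per gene list, subunit synthesis in complexes, profiles around start and stop codons, codon occupancy, and shares of signal in RNA genes were not analysed here. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered the pseudocount, density limits, capped signal, scaling, window length, cluster gap, read minimum, peak definition, and leaving out each replicate.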

Results

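Ribosome-protected fragments were measured in exponentially growing Escherichia coli K-12 MG1655, a laboratory wild-type strain, in rich medium with glucose. The cells had been treated with chloramphenicol, an antibiotic that stops elongation by bacterial ribosomes. The group comprised 2 biological replicates with 6418583 and 8615848 reads. The plus strand held 46.4% of the reads in replicate 1 (95% Wilson interval 46.4% to 46.5%) and 45.4% in replicate 2 (45.3% to 45.4%). Signal was present at 12.2% of the strand-specific positions in replicate 1 and at 16.5% in replicate 2. The 1000 positions with most signal held 30.3% ± 1.26 of the reads (SD, n = 2). Positions are those of the files, whose genome build is not given in the sources used here, and regions are named by strand and position.

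The level of ribosome-protected signal along the chromosome was examined first. Signal was concentrated in few regions. The minus-strand cluster from 3437614 to 3451668, 14055 nt long, held 16.9% ± 0.156 of all reads (SD, n = 2), and the plus-strand cluster from 4173854 to 4187599 held 9.94% ± 0.110. It was followed by the minus-strand cluster from 3468142 to 3473028 with 3.41% ± 0.225. The 20 clusters with most reads together held 54.6% ± 0.939 of the signal, and the 100 with most reads held 76.7% ± 1.18. In intervals of 100 kb, the minus strand from 3400001 to 3500000 held 20.6% ± 0.326 and the plus strand from 4100001 to 4200000 held 10.9% ± 0.363. Of the 92 intervals on both strands, 48 held under 0.5% each.

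**Figure D1:**
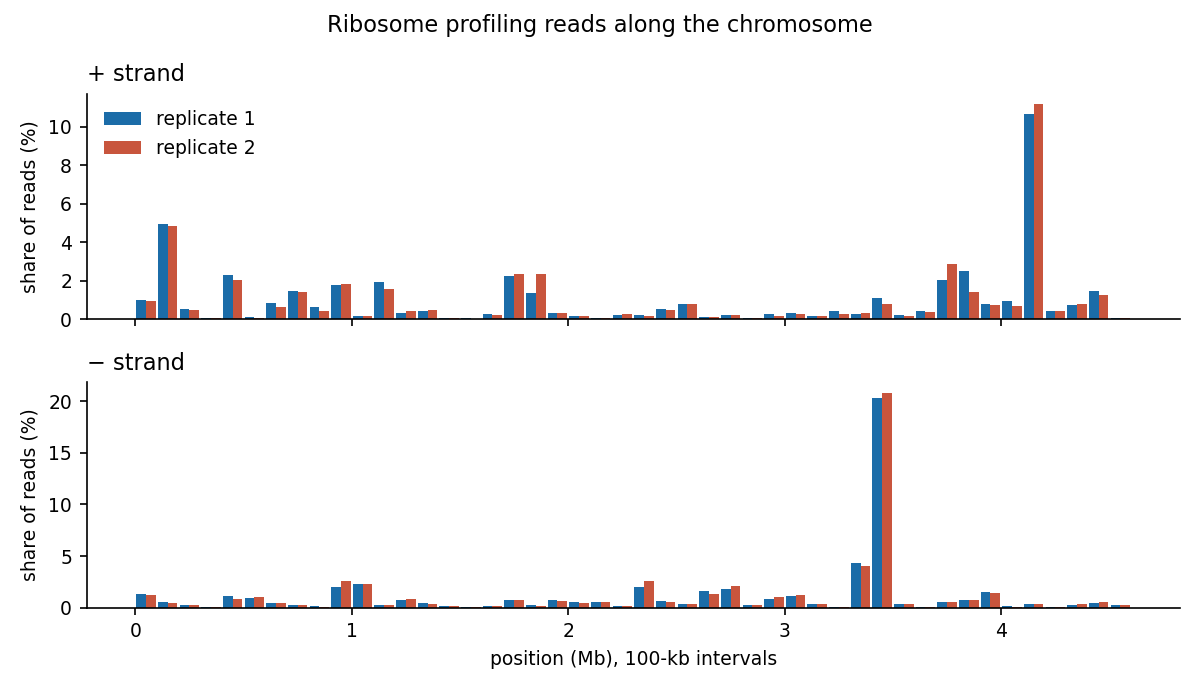
Share of all reads (%, vertical axis) in 100-kb intervals along the chromosome (Mb, horizontal axis), for the plus strand above and the minus strand below, with 1 bar per replicate. The minus-strand interval from 3400001 held 20.3% and 20.8% of the reads in the replicates, and the plus-strand interval from 4100001 held 10.7% and 11.2%.

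Density per cluster covered a wide range. Of 19164 clusters, 1449 had at least 100 reads in each replicate, 725 on the plus and 724 on the minus strand, and these held 98.3% of the reads in each replicate. Their median length was 820 nt. The densest was the plus-strand cluster from 1755417 to 1755715, at 55459 ± 983 reads per kb per 1000000 reads (SD, n = 2). The plus-strand cluster from 3717922 to 3718466 had a density of 39806 ± 10404, and the minus-strand cluster from 20779 to 21198 had 25485 ± 80.2. A density of 17827 ± 231 was reached by the minus-strand cluster from 1018209 to 1019397. The 2 long clusters with most reads were also among the 20 densest, at 12008 ± 111 from 3437614 and 7230 ± 79.8 from 4173854. The remaining clusters of the 20 lay between 6717 and 24381. The 5 least dense clusters lay between 13.8 and 16.8, led by the plus-strand cluster from 32967 to 34036 at 13.8 ± 1.27. All 5 lay close to the minimum of 100 reads in replicate 1. Clusters with fewer reads were left out, so the lower end of the range depends on that minimum. The median over clusters was 100.7.

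**Figure D2:**
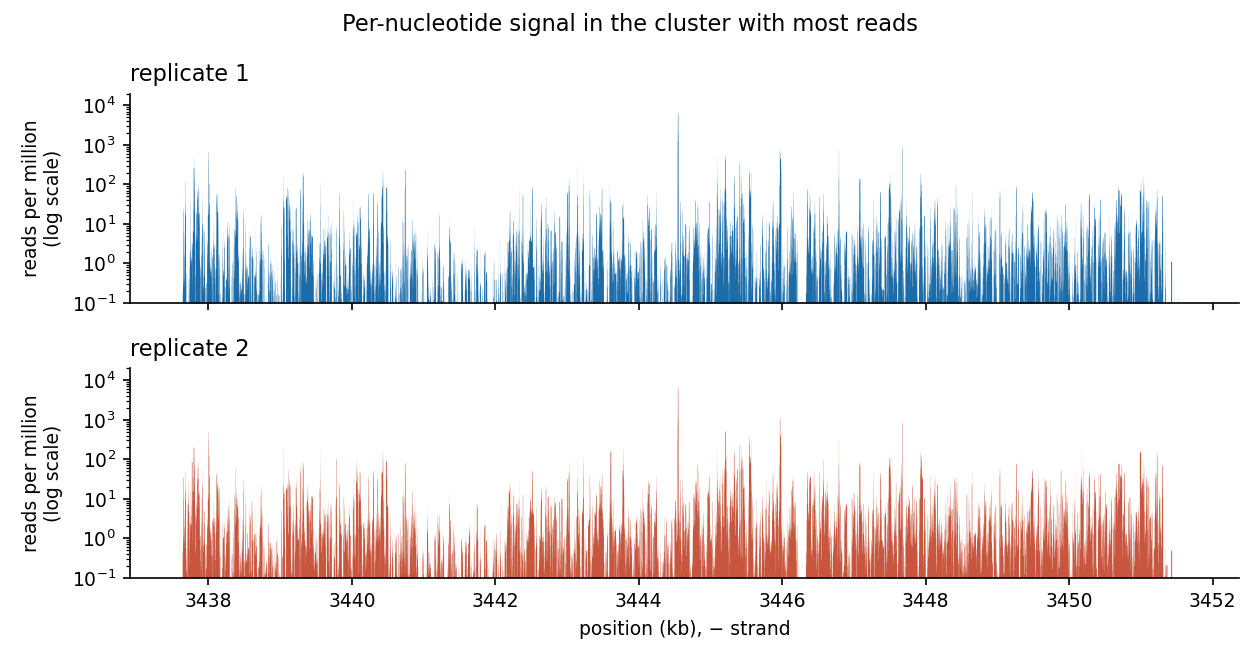
Signal per nucleotide (reads per 1000000 reads, log scale, vertical axis) on the minus strand from 3437614 to 3451668 (kb, horizontal axis) in replicate 1 (above) and replicate 2 (below). The highest position, 3444540, stood at 549 and 545 times the cluster's mean in the replicates.

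Which regions stood apart from the typical level was examined over windows of 300 nt. Of 30930 windows on both strands, 8226 (26.6%) were measured, and the median is that of measured windows only. Windows under the density limit were left out, so the windows called below do not count all low regions. Of the 8226 measured windows, 1602 (19.5%) lay at least 4 times above the median and 639 (7.77%) at least 4 times below it in both replicates. All of these had limma's adjusted p under 0.05, so the test removed none and the numbers rest on the limit of 4 times. The windows above held 89.4% ± 0.174 of all signal (SD, n = 2), and those below held 0.140% ± 0.00272. The window from 3444301 to 3444600 on the minus strand was highest, with a log2 difference from the median of 11.86 (SE 0.24, limma adjusted p = 2.42e-05). It was followed by the plus-strand window from 4178401 to 4178700, at 10.49 (SE 0.25, limma adjusted p = 2.42e-05). The plus-strand window from 3717901 to 3718200 stood at 10.36 (SE 0.26, limma adjusted p = 2.42e-05). With a lower limit of density of 50, 486 windows were called above the median. With that limit or with a pseudocount of 10, no measured window could lie 4 times below the median, so none could be called there. Windows of 100 nt gave 3838 above and 1487 below, windows of 1000 nt gave 562 and 245, and a single replicate gave 1795 to 1802 and 1031 to 1038.

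The replicates were compared over the same windows and over clusters. Windows had a Pearson r of 0.957 (95% bootstrap interval 0.949 to 0.964) and a Spearman rho of 0.937 on the log2 scale, which are across windows of 1 chromosome and not across independent replicates. The SD of the log2 difference was 0.66, and 67.0% of windows differed by less than 1.5 times. Over clusters, r was 0.961, and 88 of 1449 (6.07%) differed over 2 times, 30 higher in replicate 2 and 58 higher in replicate 1. This number was 30 with at least 500 reads per cluster and 159 with clusters joined over 20 nt. The median log2 difference over clusters, replicate 2 less replicate 1, was -0.16. The split by direction was not corrected for this general difference, which favours clusters higher in replicate 1. The labels name 2 biological replicates.

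Some of the clusters that differed most lay near each other. On the plus strand, the cluster from 167645 to 169009 had densities of 103.9 and 15.8 in replicates 1 and 2, and its neighbour from 169073 to 169725 had 150 and 29.0. The plus-strand clusters from 2227000 to 2227069 and from 2228635 to 2229118 had 563 and 184, and 93.3 and 30.7. In the opposite direction, the plus-strand cluster from 3492019 to 3494337 had densities of 19.1 and 78.6. On the minus strand, the cluster from 950454 to 953685 had 1081 and 3602, and that from 4377030 to 4380428 had 87.0 and 298. With 1 library on each side, these differences were not tested.

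**Figure D3:**
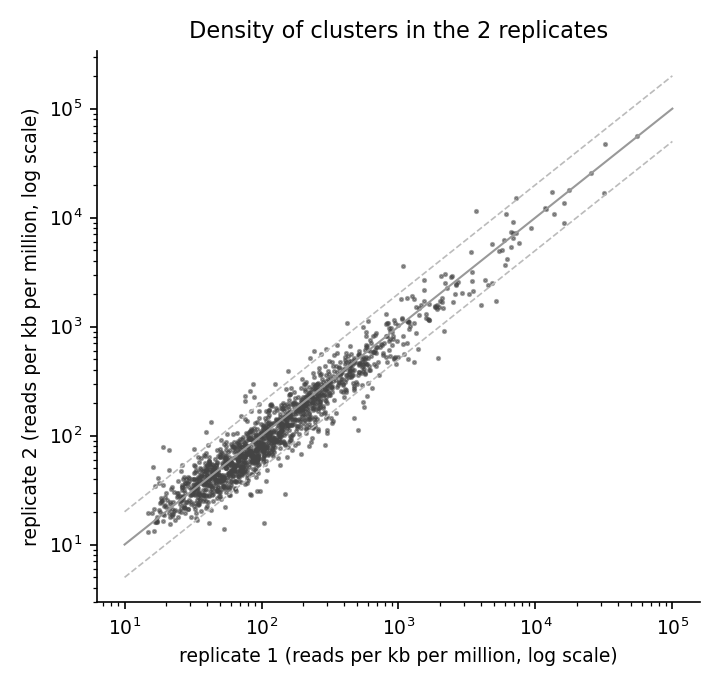
Density of the 1449 clusters (reads per kb per 1000000 reads, log scales) in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with 1 point per cluster, a solid line of equality and dashed lines at differences of 2 times. 88 clusters lie outside the dashed lines.

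Because chloramphenicol was added before harvest, the distribution of signal along clusters was measured within each library. Among 1104 clusters, 400 (36.2%) had less signal in the first 150 nt than in the rest and 286 (25.9%) had more, at limma's adjusted p under 0.05. The median log2 ratio was -0.26 in replicate 1 and -0.20 in replicate 2. Cluster starts were set by where signal began and need not be start codons, so less signal there may in part follow from the definition. The median ratio was -0.12 with clusters joined over 20 nt and -0.49 over 100 nt. The minus-strand cluster from 1988917 to 1989704 had the highest called ratio, 5.01 on the log2 scale (SE 0.27, limma adjusted p = 0.00229). The plus-strand cluster from 1185058 to 1186288 followed at 4.88 (SE 0.22, limma adjusted p = 0.00229). The minus-strand clusters from 3734334 and from 2722400 stood at 4.68 and 4.59, and the other 6 of the 10 highest lay between 3.88 and 4.31. Most of these 10 clusters held a shared peak within the first 150 nt. In the cluster from 1185058 this peak lay at 1185108, at 207 and 197 times the cluster's mean in the replicates. Such ratios therefore include local peaks, and how far the ratios depend on the peaks was not tested. The lowest called ratios were limits, since the share of the mean added to both parts bounds them by cluster length. The plus-strand cluster from 3882177 to 3882773 stood at -3.88 (SE 0.22, limma adjusted p = 0.00229) with a lowest possible value of -3.89. The clusters from 3963603 on the plus strand and from 3809241 on the minus strand had -3.87 and -3.74, with lowest possible values of -3.89 and -3.76. The direction of the median was not stable. It was 0.035 when the first 300 nt were compared with the rest in 926 clusters of at least 600 nt, where 308 had less signal and 326 more. In the same 926 clusters, the first 150 nt gave -0.27, with 340 less and 241 more. When medians over positions replaced means, the median was 0, limma called 0 clusters and 357 had an unadjusted p under 0.05. As 32.4% and 5.80% of the ratios were then exactly 0 in the replicates, this alternative says little on direction.

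Signal at the 3′ ends was compared in the same way. In the last 150 nt, 559 of 1104 clusters (50.6%) had less signal than in the rest and 130 (11.8%) had more, at limma's adjusted p under 0.05, with a median log2 ratio of -0.86 ± 0.14 (SD, n = 2). Averaged over clusters, the relative signal was 1.19 ± 0.0393 of the mean in the 1st of 10 equal parts of the length and 0.761 ± 0.00101 in the 10th (SD, n = 2). The high value of the 1st part held for means only, since its medians over clusters were 0.673 and 0.691 in the replicates, below the 0.750 and 0.790 of the 2nd part. In the 10th part the medians were 0.395 and 0.472. Cluster ends were set by where signal stopped, and the median ratio was -0.56 with clusters joined over 20 nt and -1.46 over 100 nt. When medians over positions replaced means, it was -0.15 (0 in replicate 1 and -0.30 in replicate 2), limma called 0 clusters and 306 had an unadjusted p under 0.05, while 38.4% and 5.98% of the ratios were exactly 0.

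**Figure D4:**
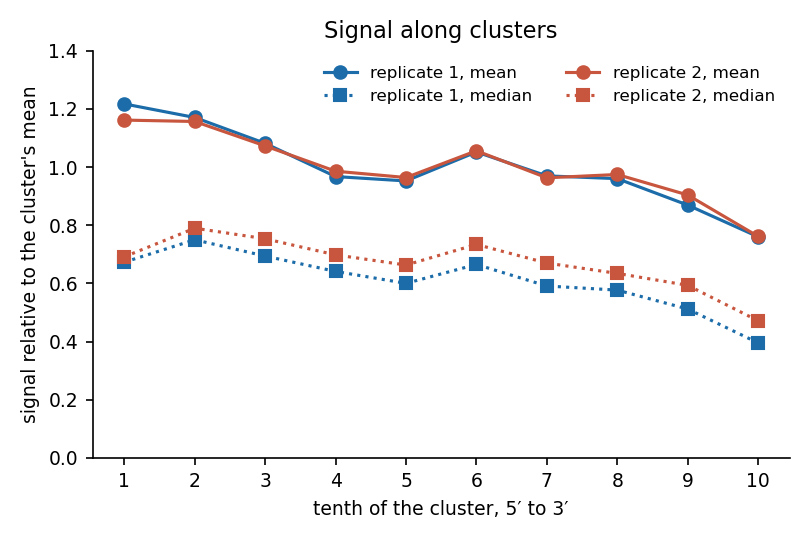
Signal relative to the cluster's mean (vertical axis) in 10 equal parts of the cluster from 5′ to 3′ (horizontal axis) over 1104 clusters, with means (circles, solid lines) and medians (squares, dotted lines) of each replicate. The mean over both replicates was 1.19 in the 1st part and 0.761 in the 10th.

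Ribosomes move in steps of 3 nt, and whether the signal resolved codons was examined through its period. At 3 nt, 60.7% of 2527 adjoining pairs of pieces had the same phase in replicate 1 and 66.9% in replicate 2, against 31.6% to 34.9% at the 8 control periods. Power at 3 nt was 2.28 and 2.84 times the mean of the control periods. The same piece had the same phase in both replicates in 84.2% of 3910 pieces, against 63.1% to 67.7% at the control periods. The mean share of both replicates was 63.8% at a distance of 300 nt and 38.8% at 2400 nt. The minus-strand cluster from 3468142 to 3473028 kept its phase in both replicates in 12 of 14 adjoining pairs, and the cluster from 3437614 did so in 16 of 45.

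**Figure D5:**
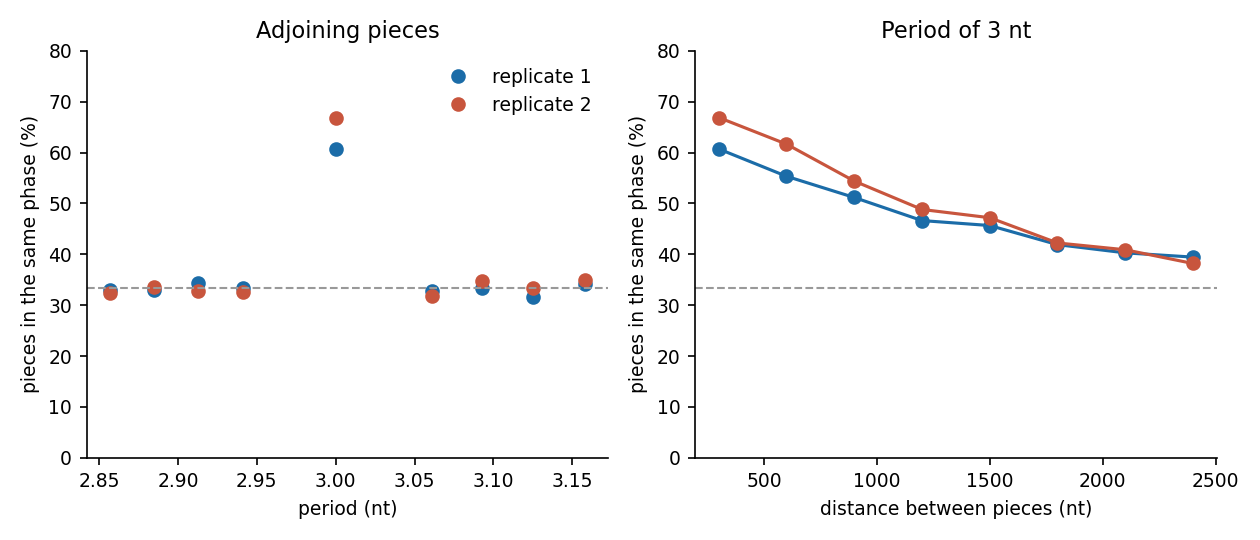
Share of pairs of pieces in the same phase (%, vertical axes) for adjoining pieces by period (nt, left) and at a period of 3 nt by distance (nt, right), per replicate, with the chance level of 33.3% dashed. At 3 nt, adjoining pieces reached 60.7% and 66.9%, and at 2400 nt 39.4% and 38.2%.

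High peaks at single positions recurred between the replicates. Among 1020 clusters, 3427 peaks were found in replicate 1 and 2952 in replicate 2, and 2261 were found in both, against a mean of 123 and a highest value of 149 in 100 random shifts. Shared peaks were ranked by the lower of their values in the 2 replicates. The highest, at 3444540 on the minus strand, stood at 547 ± 2.66 times its cluster's mean (SD, n = 2). The peak at 4020012 on the plus strand stood at 336 ± 6.23 times, and the peak at 2632066 on the minus strand at 252 ± 7.05 times. The plus-strand peak at 3353920 differed more, at 499 and 240 times in replicates 1 and 2. The other 6 of the 10 highest had means between 202 and 286 times. The number of shared peaks was 879 with a threshold of 20 times the mean and 5587 with 10 times the median of positions with signal.

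Signal on the strand opposite to a cluster was rare. It made up 0.237% ± 0.0711 of the reads on both strands of the 1020 clusters (SD, n = 2), and 0.0304% ± 0.00559 without positions that belong to clusters of the opposite strand. The minus-strand cluster from 656677 to 657169 held 442 and 483 reads in the replicates, and 97.1% and 96.3% of the reads at its positions lay on the plus strand. These were 14835 and 12616 of the 17872 and 15602 opposite-strand reads over all 1020 clusters. Most of the share of 0.237% thus came from this single cluster. Its positions overlap the plus-strand cluster from 656493 to 656753, which held 27163 and 30737 reads. In 4 clusters, over 10% of the reads lay on the opposite strand in both replicates. Besides the cluster from 656677, these began at 3715323 and 3795819 on the plus strand and at 3774070 on the minus strand. Outside all clusters with at least 100 reads lay 1.71% ± 0.0356 of the reads.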

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

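Of 117 alternative values for 15 results, 56 stayed within the limits set, 60 moved further and 1 changed sign. The limits were 1.5 times for counts and the mean ± SD of the replicates for most other values. For the window correlation and the SD of the log2 difference they were bootstrap intervals over blocks of the chromosome. A single replicate always lies within the mean ± SD of both, so leaving out a replicate could not move values judged that way and says nothing on their stability. Window lengths, cluster gaps, the minimum of 500 reads, the masked opposite strand, 150 nt in clusters of at least 600 nt and all values for the last 150 nt were chosen after the data were examined. Except where a change follows from fewer or more items entering, the cause was not tested. Not run were the alternatives that need annotated genes: those on the ends of coding sequences, shared positions, gene lists, complexes, start and stop profiles, and codon occupancy. No paired analysis was possible because there was 1 group. Depth limits the low windows, where a density of 5 stands for 9.63 reads in replicate 1 and 12.9 in replicate 2.

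The median ratio for the first 150 nt changed sign with 300 nt in clusters of at least 600 nt (0.035, with 308 clusters less and 326 more). With 150 nt in the same clusters it stayed at -0.27 (340 less and 241 more), so the length limit alone did not change the sign. It was 0 with medians over positions, -0.42 at density at least 100, -0.35 at 500 reads, -0.12 with clusters joined over 20 nt and -0.49 over 100 nt, and leaving out a replicate gave -0.26 to -0.20. The last 150 nt gave -0.52 with 300 nt and -0.89 with 150 nt in clusters of at least 600 nt, -0.15 with medians, -1.19 at density at least 100, -1.10 at 500 reads, -0.56 at 20 nt and -1.46 at 100 nt, and -0.96 to -0.77 without a replicate. Called clusters with less and with more signal at the 5′ end numbered 212 and 149 at density at least 100, 261 and 179 at 500 reads, and 233 and 190 with gaps of 20 nt. At the 3′ end they numbered 296 and 47, 363 and 61, and 295 less with gaps of 20 nt. With medians all 4 counts were 0, with 357 and 306 clusters at an unadjusted p under 0.05 in limma, but 32.4% and 5.80% of the ratios at the 5′ end and 38.4% and 5.98% at the 3′ end were then exactly 0 in the replicates.

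Windows over the median numbered 486 at density at least 50, 8292 without a filter, 3838 at 100 nt and 562 at 1000 nt, and 1795 to 1802 in 1 replicate, without a test. Those below numbered 0 at density at least 50, without a filter and with a pseudocount of 10, 385 with capped signal, 1487 at 100 nt, 245 at 1000 nt, and 1031 to 1038 in 1 replicate, since agreement of both was then not required. The 3 counts of 0 follow from the settings, since a call needs a log2 difference of -2 and the lowest possible ones in the replicates were -1.91 and -1.85, -0.60 and -0.47, and -1.87 and -1.83 in that order. The window correlation was 0.949 at density at least 50, 0.975 without a filter, 0.934 at 100 nt and 0.970 at 1000 nt. The SD of the log2 difference was 0.57, 0.61, 0.83 and 0.53 in the same order, 0.68 and 0.53 with pseudocounts of 0.1 and 10, and 0.63 with capped signal.

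Clusters over 2 times apart numbered 30 at 500 reads and 159 with gaps of 20 nt. The 20 clusters with most reads held 50.8% at 20 nt and 55.7% at 100 nt, and 53.9% to 55.3% in 1 replicate. The 3-nt phase was kept in 70.7% of pairs at 20 nt, and in 60.7% to 66.9% in 1 replicate. Shared peaks numbered 5587 against the median, 879 at 20 times and 986 at density at least 200, and 2952 to 3427 were found in 1 replicate. Opposite-strand signal was 0.369% with clusters widened by 50 nt and 0.0304% masked, and 0.187% to 0.287% in 1 replicate.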

Other observations

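All tests weighed here were chosen after the results had been seen, as were the distances and lengths they use.

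The longest cluster, on the minus strand from 2388028 to 2403153, was 15126 nt long and kept its 3-nt phase in both replicates in 21 of 45 adjoining pairs. The plus-strand cluster from 122001 to 129368 did so in 17 of 23 and the minus-strand cluster from 3309418 to 3316243 in 16 of 21. With pieces put in 4 classes at the quartiles of the density of their cluster, in the least dense class the phase was kept in 50.1% and 56.0% of pairs in the replicates, and in the densest class in 65.5% and 70.2%.

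Reads that stood alone were spread over 1 to 23 nt in replicate 1 and over 1 to 31 nt in replicate 2, with a median of 6 nt in both. None of 19531 lone reads of replicate 1 was spread over more than 23 nt, which allows up to 0.0154%, against 307 of 27953 (1.10%) in replicate 2.

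The 7 longest stretches without signal on either strand in both replicates were 2932 to 3543 nt long, and the next was 2509 nt. The longest ran from 4035121 to 4038663. Each of the 7 had a second stretch of at least 1400 nt without signal within 600 nt, as did 11 of 39 other stretches of at least 1500 nt (28.2%), of which 7 were the partners themselves. Since the 7 were also longer than all others, length and pairing cannot be told apart, and low expression stays open. The gene table of ASM584v2 names 7 genes for the large ribosomal RNA, and all 7 of the stretches came with such a partner. Reads from ribosomal RNA operons may have been left out before deposit, by a filter or because they match several places, which these values do not separate. With 1 group, no biological explanation was tested against other samples.

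Neighbouring clusters on the same strand, at most 500 nt apart, had replicate differences with a Pearson r of 0.198 across 491 pairs (95% bootstrap interval 0.083 to 0.318), where pairs that share a cluster are not independent. Reads divided at random between the depths gave at most 0.128 in 100 draws, which argues against counting noise. On opposite strands r was 0.060 (-0.069 to 0.187, 235 pairs), and since the intervals overlap, a trend common to both strands of a region cannot be told apart from one along transcripts. The differences had the same direction in 55.0% of the 491 pairs, against 50.2% of pairs 50 to 60 kb apart. Pairs on the same strand can include clusters little more than 50 nt apart, which a wider gap limit would join, and these were not set apart. On the same strand, r was 0.083 (0.002 to 0.174) above 500 and up to 2000 nt, and 0.0020 above 2000 and up to 10000 nt. Transcripts shared by neighbours and differing between the cultures are a possible explanation that was not tested.

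The 3-nt phase was kept by 63.8% of adjoining pieces, and control periods reached at most 34.9%. The 63.8% is the pattern itself, so it does not test whether the way reads were spread over positions had a part in it. Simulated clusters without a reading frame, with reads spread evenly over widths of lone reads from replicate 1, kept the phase in 33.8% of pairs. Even spreading of this kind alone thus stayed near the chance level. How reads in other runs were spread was not tested, so other ways of spreading stay open. Codons also repeat in the sequence every 3 nt, so a sequence preference of cutting or ligation could give such a phase without movement of ribosomes. The 34.9% at control periods does not bear on this, and without RNA fragments free of ribosomes it cannot be told apart from ribosome steps.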
